A study of Homo sapiens with 64 samples.

How the data were processed

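BEAS-2B cells were left untreated or given budesonide, formoterol or both, and RNA collected at 1, 2, 6 and 18 h was hybridised to 64 Affymetrix arrays, 4 for each of 16 groups. The deposited values are log2 expression per probe set from RMA, a method that corrects background, normalizes and summarises probes, per the submitters' processing notes, and its version is not given in the sources used here. Whether all arrays were normalized together is not given in the sources used here. If they were, their distributions were made alike and a change shared by most genes would not be seen. The array medians lay between 4.87 and 4.95 and the interquartile ranges between 4.04 and 4.39, with values from 1.16 to 13.9. Arrays give no read depth, and their number limits the precision.

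Of 49395 probe sets, 44994 carried 1 gene symbol in the platform annotation, 1832 several and 2569 none, and symbols were updated through gene identifiers. Probe sets with several symbols or none were left out of the gene tests. Each gene was represented by the probe set with the highest mean over all arrays, which gave 18132 genes, 11735 of them with more than 1 probe set. Of 155 pairs of gene and comparison that the naming rule below gave, 120 had several probe sets. These ran in one direction in 110 pairs and not in the other 10, which were PRDM1 and EGR1 for the combination at 1 h, EGR1 and HMGA2 for the combination against budesonide at 2 h, KLF9, NPTX1 and ADH1B in the interactions at 2, 6 and 18 h, CRISPLD2 for formoterol at 6 h, and HDAC9 for formoterol at 6 and 18 h. This check compared direction only, and sizes could differ widely. With budesonide at 6 h the probe sets of CNR1 changed by 1.92 to 6.79, those of CACNA2D3 by 0.022 to 4.55 and those of TSC22D3 by 3.85 to 5.47.

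Tests were made with limma 3.58.1 in R 4.3.3, with version 1.17.8 of the data.table package, and figures were drawn with matplotlib 3.10.9 in Python 3.11.15. One linear model held a mean for each of the 16 groups, with 48 residual degrees of freedom and empirical Bayes moderation with an intensity trend. At each time each treatment was compared with untreated cells, the combination with each drug, and the interaction was tested as the combination minus budesonide minus formoterol plus untreated. Untreated cells at 18 h were compared with those at 1 h, which made 25 contrasts, and a moderated F test asked whether a treatment's effect differed between times. Genes were called at a two-sided Benjamini-Hochberg adjusted p under 0.05 within each contrast, and the number also changed at least 2-fold was counted. Gene symbols stand for probe sets, and no coordinates were used.

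The genes named were drawn from a rule that gives, for each treatment, the combination against budesonide and the interaction at each time, the 4 highest and the 4 lowest changes among called genes. These had to be changed at least 2-fold and to have a group mean at or above the median of all probe sets, 4.90. For comparisons of a pair of groups all 4 arrays of one group also had to lie above all 4 of the other. Members of the gene lists and the glucocorticoid receptor gene NR3C1 could be named too. The rule gave 155 pairs of gene and comparison, of which the text prints a part. Of these pairs 13 had a group mean below 3.02, the lower quartile of all probe set values. The 21 gene lists covered glucocorticoid-induced, cAMP and CREB-induced, immediate early, cytokine and chemokine, NF-kappaB, interferon-stimulated and MAPK feedback genes, and regulators of G-protein signalling. They also covered cAMP machinery, clock, cell division, extracellular matrix, fasting, metallothionein, cholesterol, heat shock and unfolded protein response, and epithelial junction genes, leukocyte, endothelial, and fibroblast and smooth muscle markers, and ribosomal proteins. Lists were tested with limma's camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over all 336 tests. Members were counted by the gene test, with adjustment over all genes and over the list alone. The design, naming rule, gene lists and all alternatives but those named below as added were chosen before the data were examined.

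The labels number the replicates 1 to 4 in every group and do not say what a number shares. Deviations from the group means of same-numbered arrays correlated above 0.1 for every pair in 20 of 25 contrasts. Mean correlations were, for example, 0.364 for budesonide at 1 h and 0.663 at 2 h. In these contrasts the numbers thus pair the arrays, but the main fit had no term for the replicate number. Its counts, SE and p-values are therefore unpaired, and pairing enters only in the fits with a block. Alternatives were the replicate number as a block, each array centred on its median, quantile normalization repeated, dim genes left out, no intensity trend, the mean of all probe sets of a gene, a fit of the compared arrays alone, additivity on the linear scale and each array left out in turn. A block within each time and a fit without all replicate 1 arrays were added after seeing the data.

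The steps were tested on simulated data with 200 of 18132 genes changed. For budesonide at 6 h, 86.6%, 97.0% and 100% of genes changed 1.5, 2 and 3-fold were recovered, with 15 false calls among 204. For the interaction at 6 h the shares were 52.2%, 95.5% and 100%, with 12 false calls among 177. For the budesonide effect over times they were 49.3%, 97.0% and 100%, with 5 among 169. For budesonide at 6 h camera called the 1 changed list and 0 of the 20 unchanged lists. The simulated noise was drawn independently for every gene and array, without correlation between genes or between same-numbered arrays. These false calls therefore do not measure those to be met in the real arrays.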

Results

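Gene expression was measured in BEAS-2B, an immortalised line of human bronchial epithelial cells, after exposure to drugs used by inhalation in asthma. Budesonide, a glucocorticoid that acts through the nuclear receptor NR3C1, was given at 100 nM. Formoterol, a long-acting bronchodilator agonist that raises cyclic AMP, was given at 10 nM. Untreated cells, cells given either drug and cells given both were collected after 1, 2, 6 and 18 h, with 4 arrays in each of the 16 groups. The 64 arrays had log2 medians between 4.87 and 4.95, and 18132 genes were tested. Changes below are log2 differences ± SE from limma with n = 4 arrays per group, and named changes passed the Benjamini-Hochberg threshold unless a sentence says otherwise. The labels call the replicates independent determinations, p-values measure the spread between these samples, and the number of arrays limits the precision. The main fit did not pair arrays by replicate number, so its SE and p-values are unpaired. The files used here give no detection calls. Where a group mean lay below 3.02, the lower quartile of all probe set values and a level chosen after the data were seen, it was read as not told from background, and a difference from it is given as a lower bound. As levels of different probe sets are not comparable, the level of 3.02 is a rough guide only. Groups just above it, such as IL11 with the combination at 6 h (3.24), may lie near background too, and sizes are printed for them without a bound. Sizes and bounds hold for the probe set used for each gene, and other probe sets of a gene could show far smaller changes.

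The first principal component of the arrays held 35.1% of the variance and separated budesonide-containing groups from the others at 6 and 18 h. The mean of budesonide arrays moved from −8.02 on this component at 1 h to 32.29 at 18 h, while the means of the untreated groups lay between −11.88 and −7.95. The second component held 15.99% and was highest in the combination at 2 h, with a mean of 25.12 ± 2.67 (SD, n = 4) against −8.47 ± 2.88 in untreated cells. Formoterol arrays at 18 h had a mean of −13.29 ± 0.81 on the second component, against an untreated mean of −14.09. The 3' minus 5' signal of beta-actin, a measure of RNA quality, was highest in replicate 1 in all 12 groups at 1, 6 and 18 h (1.52 to 2.21 in log2 units) and in replicate 3 in the 4 groups at 2 h (1.35 to 1.61). A fit without the replicate 1 arrays, chosen after seeing the data, is named below where it ended the call of a gene named here or moved a count by over 1.5 times. At 2 h that fit kept the replicate 3 arrays, the highest there, so at that time it is no test of this measure.

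**Figure D1:**
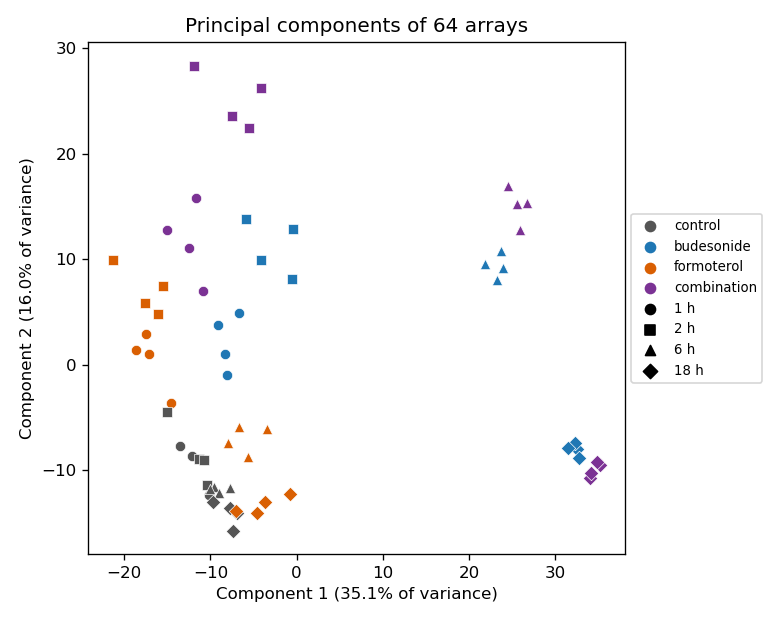
Position of each of the 64 arrays on the first component (horizontal axis, 35.1% of variance) and the second component (vertical axis, 15.99%), both in log2 units; colours mark treatments and shapes mark times. Arrays with budesonide, alone or in the combination, lie to the right of all others at 6 and 18 h.

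Budesonide against untreated cells asked what the glucocorticoid alone changes. At 1 h TSC22D3, which encodes the glucocorticoid-induced leucine zipper protein GILZ, rose by 3.94 ± 0.11 and the transcription factor KLF4 rose by 3.91 ± 0.24. DDIT4, an inhibitor of mTORC1 signalling, rose by 2.91 ± 0.15, and the thiamine transporter gene SLC19A2 rose by 2.85 ± 0.13. The immediate early gene IER3 fell by 1.90 ± 0.13, the AP-1 subunit JUN fell by 1.62 ± 0.10, the cytokine IL6 fell by 1.58 ± 0.19 and IL11 fell by 1.36 ± 0.20. At 2 h RGCC, a regulator of the cell cycle, and KLF9, a transcription factor, stood 4.08 ± 0.18 and 3.67 ± 0.14 above untreated cells, and the chemokine CCL2 fell by 2.12 ± 0.16. By 6 h the cannabinoid receptor CNR1, at 2.05 in untreated cells, was higher by at least 6.79 ± 0.16, RGCC by 5.34 ± 0.18 and the calcium channel subunit CACNA2D3 by 4.55 ± 0.18, and TSC22D3 averaged 11.69 ± 0.11 (SD, n = 4) against 6.49 ± 0.07 in untreated cells. TNFRSF11B, the decoy receptor osteoprotegerin, fell by 3.64 ± 0.19 at that time and the natriuretic peptide NPPB fell by 2.95 ± 0.16. At 18 h CNR1 was higher by at least 7.16 ± 0.16 and the tetraspanin TSPAN8, at 2.19 in untreated cells, by at least 5.39 ± 0.19. The carboxypeptidase CPA4 fell by 4.22 ± 0.21, CRHBP, which binds corticotropin-releasing hormone, fell by 3.48 ± 0.16 or more, to 2.66, and F3, the initiator of coagulation, fell by 3.47 ± 0.17.

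Across all genes, limma called 181 genes at 1 h (121 higher, 60 lower), 715 at 2 h (306 higher, 409 lower), 2583 at 6 h (1110 higher, 1473 lower) and 3325 at 18 h (1552 higher, 1773 lower). At least 2-fold changes were seen in 66, 145, 398 and 483 of them. The glucocorticoid receptor gene NR3C1 itself fell by 0.48 ± 0.08 at 2 h, fell by 1.05 ± 0.08 at 6 h and fell by 0.94 ± 0.08 at 18 h. With the replicate number as a block within each time, a setting chosen after seeing the data, 312, 1379 and 4081 genes passed at 1, 2 and 6 h. With only the compared arrays in the fit, 436 passed at 2 h. One array stood apart from the other 3 of its budesonide group for IER3 and TSC22D3 at 1 h, TXNIP at 2 h and LTBP1 at 18 h. Among untreated cells this held for C11orf96 and DUSP1 at 1 h and CD200, EGR1, PTGS2 and TSC22D3 at 2 h.

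Among the gene lists, 18, 22, 24 and 21 of the 25 glucocorticoid-induced genes rose at 1, 2, 6 and 18 h (20, 22, 24 and 22 adjusted over the list alone; camera adjusted p = 4.89e-179, 1.01e-150, 2.19e-72 and 2.21e-42). The immunophilin FKBP5 rose by 1.59 ± 0.11 at 2 h and 3.05 ± 0.11 at 6 h, the NF-kappaB inhibitor NFKBIA rose by 2.63 ± 0.14 at 1 h, and the cell cycle inhibitor CDKN1C rose by 3.12 ± 0.25 at 6 h. Of the 21 metabolic genes of the fasting response, 3, 10, 12 and 11 rose and 0, 1, 3 and 3 fell (6, 10, 12 and 11 rose and 0, 2, 3 and 3 fell adjusted over the list alone; camera adjusted p = 1.6e-08, 6.89e-17, 2.47e-11 and 6.02e-05). The pyruvate dehydrogenase kinase PDK4, at 2.68 in untreated cells, was higher by at least 3.56 ± 0.39 at 2 h and the transcription factor FOXO1 by 2.92 ± 0.12 at 18 h, when the glycolytic enzyme HK2 fell by 2.23 ± 0.16. Metallothioneins, which bind zinc and copper, rose in 3, 4, 7 and 5 of 9 members (4, 5, 7 and 5 adjusted over the list alone; camera adjusted p = 2.68e-18, 2.42e-18, 1.17e-11 and 2.05e-05), with MT1X at 3.27 ± 0.15 at 6 h. MAPK phosphatases and feedback inhibitors rose in 6 of 16 members at 1 h and, beside 2 that fell, in 6 at 2 h (7 rose at 1 h, and 6 rose and 3 fell at 2 h, adjusted over the list alone; camera adjusted p = 5.85e-24 and 8.25e-06). ERRFI1, an inhibitor of EGF receptor signalling, rose by 2.88 ± 0.12 at 2 h.

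Other lists shifted downwards under budesonide. Immediate early transcription factors fell in 7 of 18 members at 6 h and 8 at 18 h, with 2 and 1 higher (9 and 8 fell, with 3 and 1 higher, adjusted over the list alone; camera adjusted p = 0.000123 and 0.0018), and JUN fell by 2.81 ± 0.10 at 6 h. At 18 h 14 of 26 extracellular matrix and remodelling genes fell and 2 rose (15 and 4 adjusted over the list alone; camera adjusted p = 1.07e-06). Among them tenascin TNC fell by 1.80 ± 0.23, the lysyl oxidase LOXL2 fell by 1.61 ± 0.08 and the urokinase PLAU fell by 1.54 ± 0.11. Heat shock and unfolded protein response genes fell in 8 of 17 members at 18 h (9 adjusted over the list alone; camera adjusted p = 0.000217). Among them the asparagine synthetase ASNS fell by 0.89 ± 0.08. At 6 h 5 of these 17 fell (5 adjusted over the list alone; camera adjusted p = 0.0117, adjusted p = 0.119 with an estimated correlation). Of the 18 epithelial junction and keratin genes 7 fell and 1 rose at 18 h (7 and 3 adjusted over the list alone; camera adjusted p = 0.0278, adjusted p = 0.0829 with an estimated correlation). The tight junction gene CLDN1 fell by 1.68 ± 0.16 and the keratin KRT8 fell by 1.15 ± 0.15.

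Further budesonide calls were lost with an estimated correlation. Cytokines and chemokines fell in 5 of 26 members at 2 h (5 adjusted over the list alone; camera adjusted p = 0.0468, adjusted p = 0.297 with an estimated correlation and adjusted p = 0.0883 with the replicate block). Regulators of G-protein signalling fell in 3 of 13 members and rose in 1 at 2 h (4 and 1 adjusted over the list alone; camera adjusted p = 0.0323, adjusted p = 0.381 with an estimated correlation and adjusted p = 0.0524 with the replicate block). In the same list 5 fell and 1 rose at 18 h (5 and 1 adjusted over the list alone; camera adjusted p = 0.00877, adjusted p = 0.264 with an estimated correlation). There RGS3 fell by 1.47 ± 0.09. Cholesterol synthesis and uptake genes fell in 4 of 12 members at both 6 and 18 h (6 and 4 adjusted over the list alone; camera adjusted p = 0.00309 and 0.0124, adjusted p = 0.119 and 0.211 with an estimated correlation). For the cAMP and CREB-induced list at 1 h, 3 of 18 rose and 2 fell (4 and 2 adjusted over the list alone; camera adjusted p = 0.00162, adjusted p = 0.185 with an estimated correlation).

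**Figure D2:**
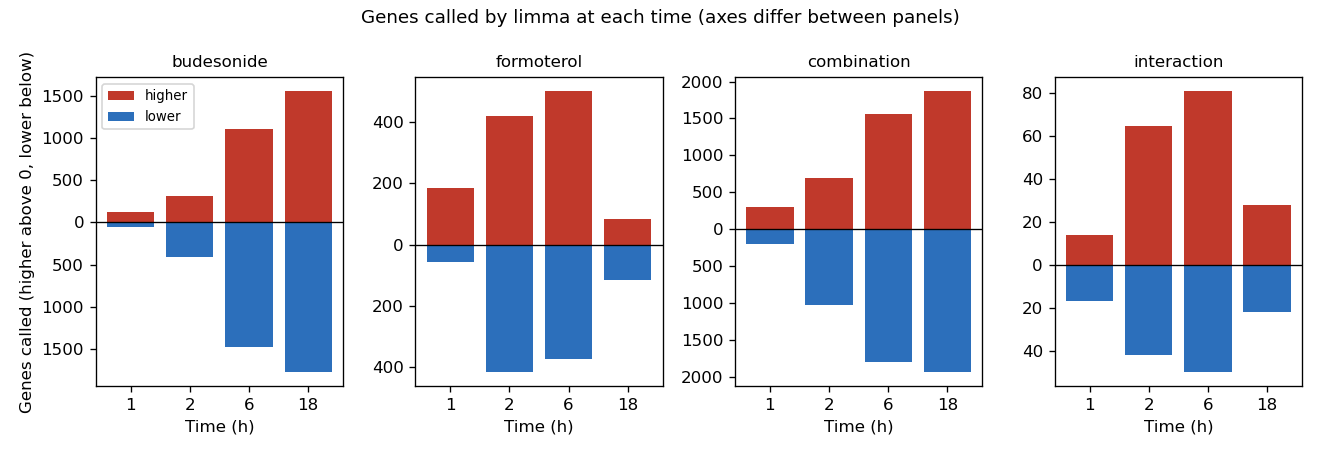
Number of genes called by limma (vertical axis, higher above 0 and lower below it) at each time in hours (horizontal axis) for budesonide, formoterol and the combination against untreated cells and for the interaction, with separate vertical scales. Formoterol calls went from 873 at 6 h to 201 at 18 h, and budesonide calls from 2583 to 3325.

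Formoterol against untreated cells asked what the agonist alone changes. At 1 h the orphan nuclear receptors NR4A3 and NR4A2 rose by 5.29 ± 0.16 and 4.70 ± 0.30, IL6 rose by 4.04 ± 0.19, and the noncoding RNA LINC00473 rose by 3.62 ± 0.20. The transcription factor EGR1 fell by 2.78 ± 0.19, the arrestin-family gene TXNIP fell by 1.71 ± 0.16 and JUN fell by 1.10 ± 0.10. At 2 h NR4A3 stood at 6.28 ± 0.16, LINC00473 at 5.13 ± 0.20 and the surface glycoprotein CD200 at 3.92 ± 0.18, and the growth factor FGF5 fell by 1.55 ± 0.17. At 6 h PDE7B, a phosphodiesterase that degrades cyclic AMP, averaged 7.54 ± 0.09 (SD, n = 4) against 3.54 ± 0.19 in untreated cells. LINC00473 was higher by 3.91 ± 0.20, SMOC1 by 3.27 ± 0.16 and CRISPLD2 by 2.95 ± 0.27, while NAV3 fell by 1.99 ± 0.20 and the histone deacetylase HDAC9 fell by 1.60 ± 0.14. At 18 h LINC00473 was 2.15 ± 0.20 higher, PDE7B 1.82 ± 0.17 and lipoprotein lipase LPL 1.44 ± 0.18, and the serpin SERPINB7 fell by 1.26 ± 0.25. NR3C1 rose by 0.48 ± 0.08 at 2 h and 0.32 ± 0.08 at 6 h, where it did not pass without untreated replicate 1 (0.27) or 2 (0.29), formoterol replicate 3 (0.29) or all replicate 1 arrays (0.25).

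The number of genes called for formoterol was 243 at 1 h (185 higher, 58 lower), 834 at 2 h (419 higher, 415 lower), 873 at 6 h (500 higher, 373 lower) and 201 at 18 h (85 higher, 116 lower). Changes of at least 2-fold were seen in 86, 128, 104 and 14 of them. With the replicate number as a block 1360 passed at 6 h, and with a block within each time, chosen after seeing the data, 557, 1637 and 1910 passed at 1, 2 and 6 h. At 18 h, where not every same-numbered pair correlated above 0.1, these fits gave 527 and 965. With only the compared arrays in the fit 470 passed at 2 h and 77 at 18 h. Single arrays moved the 18 h count: it was 93 without formoterol replicate 4, 117 without formoterol replicate 2, 121 without untreated replicate 2 and 348 without formoterol replicate 1. Formoterol replicate 4 at 18 h had a residual SD of 0.232, the highest of the 64 arrays. Without that array SERPINB7, at −0.97, did not pass. One array stood apart from the other 3 of its formoterol group for DUSP1 and NR4A2 at 1 h, FGF5 and PTGS2 at 2 h and LINC00473 at 18 h.

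The cAMP and CREB-induced list rose in 12, 14, 8 and 4 of 18 members at 1, 2, 6 and 18 h (14, 15, 9 and 6 adjusted over the list alone; camera adjusted p = 4.15e-104, 9.31e-70, 5.87e-14 and 1.16e-08). Besides the NR4A genes, PDE4D, a cyclic AMP phosphodiesterase, rose by 3.23 ± 0.14 at 2 h and the neurotrophin BDNF by 1.81 ± 0.13. Of the 25 glucocorticoid-induced genes, 11, 11 and 6 rose at 1, 2 and 6 h (11, 12 and 7 rose, with 0, 0 and 2 falling, adjusted over the list alone; camera adjusted p = 2.47e-40, 2.73e-26 and 2.42e-06, the last at adjusted p = 0.111 with an estimated correlation). They included the kinase SGK1 at 3.60 ± 0.12, the phosphatase DUSP1 at 2.43 ± 0.09 and RGS2, a regulator of G-protein signalling, at 3.16 ± 0.11, all at 1 h, and 3 measured genes belong to both lists. Cytokines and chemokines rose in 6 of 26 members at 1 h and 5 at 2 h, where 1 fell (6, then 6 and 1, adjusted over the list alone; camera adjusted p = 9.25e-18 and 3.62e-10). At 2 h IL11 rose by 3.90 ± 0.20 and CXCL2 by 2.63 ± 0.20. CXCL8, which encodes interleukin-8, fell by 0.67 ± 0.18 at 2 h, and did not pass with all probe sets averaged (−0.21), with the compared arrays alone (−0.67) or without untreated replicate 1 (−0.59) or 2 (−0.55), formoterol replicate 4 (−0.62) or all replicate 1 arrays (−0.63). MAPK phosphatases and feedback inhibitors rose in 5 of 16 and fell in 1 at 1 h (6 and 2 adjusted over the list alone; camera adjusted p = 3.14e-10). Among the 28 measured genes of the cAMP machinery, 3, 3 and 7 rose at 1, 2 and 6 h (3, 3 and 8 adjusted over the list alone; camera adjusted p = 0.00324, 0.00216 and 2.58e-07), and with an estimated correlation the adjusted p = 0.142, 0.119 and 0.00542.

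Some lists fell under formoterol. At 6 h 8 of 12 cholesterol synthesis and uptake genes fell (11 adjusted over the list alone; camera adjusted p = 1.88e-14). Among them the mevalonate kinase MVK fell by 0.67 ± 0.08 and the synthase HMGCS1 fell by 0.58 ± 0.11. At 18 h none of the 12 passed (0 adjusted over the list alone; camera adjusted p = 0.0323, adjusted p = 0.302 with an estimated correlation). Cell division genes fell in 7 of 24 members at 2 h and rose in 1 (9 and 1 adjusted over the list alone; camera adjusted p = 7.61e-05). The mitotic kinase AURKA fell by 0.62 ± 0.06 and the proliferation marker MKI67 fell by 0.67 ± 0.13. Heat shock and unfolded protein response genes fell in 2 of 17 members at 18 h, ASNS and HSPA5 (3 adjusted over the list alone; camera adjusted p = 0.00014). The call for immediate early transcription factors at 1 h was lost with an estimated correlation (5 rose and 3 fell of 18, 7 and 4 adjusted over the list alone; camera adjusted p = 0.0151, adjusted p = 0.118 with an estimated correlation). The same held for extracellular matrix genes at 1 h (1 of 26 rose, 2 adjusted over the list alone; camera adjusted p = 0.0375, adjusted p = 0.264 with an estimated correlation). The NF-kappaB list rose in 3 of 18 members at both 1 and 2 h (4, then 3 with 1 falling, adjusted over the list alone; camera adjusted p = 0.00137 and 0.0327, adjusted p = 0.226 and 0.498 with an estimated correlation).

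**Figure D3:**
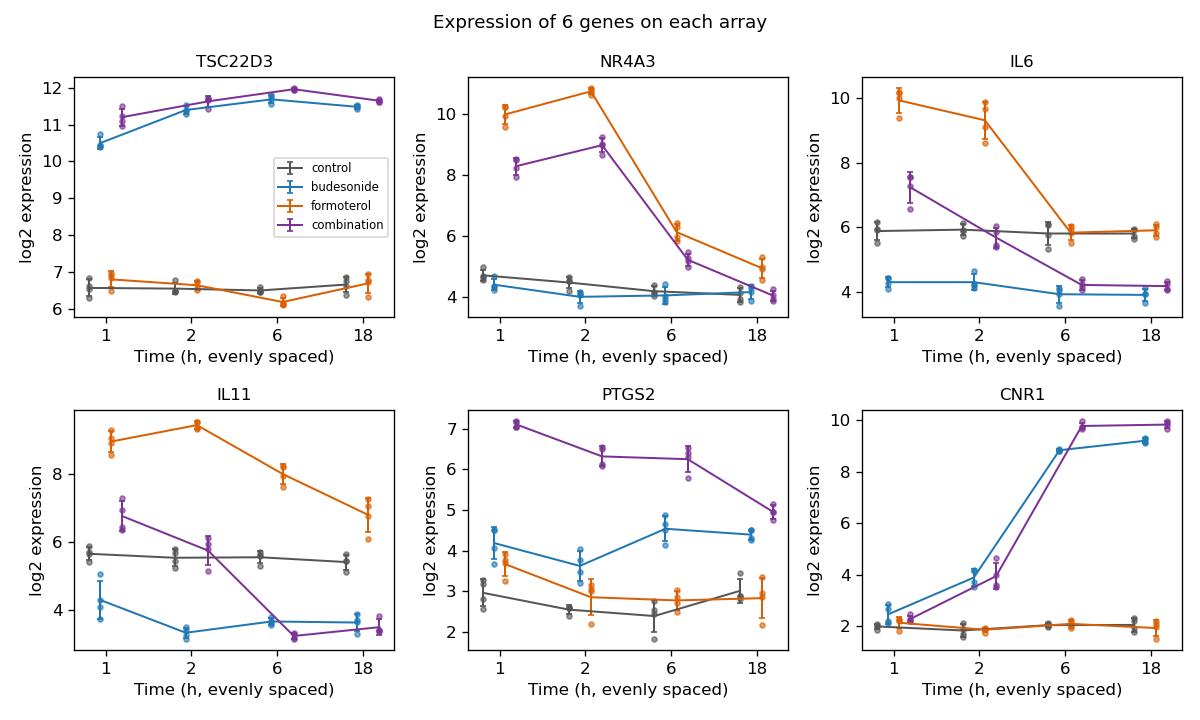
Log2 expression (vertical axis) of TSC22D3, NR4A3, IL6, IL11, PTGS2 and CNR1 at each time in hours (horizontal axis, evenly spaced); points are arrays, lines join the means of 4 arrays and bars are ± SD. NR4A3 averaged 10.76 with formoterol and 8.99 with the combination at 2 h, and CNR1 averaged 8.84 with budesonide and 2.05 in untreated cells at 6 h.

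The combination against untreated cells asked what both drugs together change. At 1 h KLF4 rose by 5.27 ± 0.24, the transcriptional repressor PRDM1 by 4.98 ± 0.23, TSC22D3 by 4.64 ± 0.11 and RGS2 by 4.54 ± 0.11. EGR1 fell by 3.38 ± 0.19, JUN fell by 2.14 ± 0.10 and the cytokine signalling inhibitor SOCS3 fell by 1.44 ± 0.23. The several PRDM1 and EGR1 probe sets did not all run in one direction. At 2 h C11orf96 was higher by 5.44 ± 0.25 and PDK4 by at least 4.89 ± 0.39, and the AP-1 gene FOSL1 fell by 2.19 ± 0.17. CNR1 was higher by at least 7.74 ± 0.16 at 6 h and at least 7.78 ± 0.16 at 18 h. TNFRSF11B fell by 4.56 ± 0.19 and EVA1A fell by 3.40 ± 0.11 at 6 h, and CPA4 fell by 4.82 ± 0.21 and the matricellular gene CCN3 fell by 3.65 ± 0.18 at 18 h. The inducible cyclooxygenase PTGS2, at 2.96 and 2.39 in untreated cells, rose by at least 4.15 ± 0.21 at 1 h and at least 3.86 ± 0.21 at 6 h. IL6 rose by 1.35 ± 0.19 at 1 h, differed by −0.25 ± 0.19 at 2 h, which did not pass, and fell by 1.59 ± 0.19 at 6 h.

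The combination changed 500 genes at 1 h (295 higher, 205 lower), 1721 at 2 h (697 higher, 1024 lower), 3366 at 6 h (1562 higher, 1804 lower) and 3807 at 18 h (1869 higher, 1938 lower) in limma. At least 2-fold changes were seen in 141, 281, 551 and 584 of them. With a replicate block within each time, chosen after seeing the data, 966 and 2794 passed at 1 and 2 h. One array stood apart from the other 3 of its combination group for TSC22D3 at 2 h and IL11 at 18 h.

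Glucocorticoid-induced genes rose in 19, 23, 24 and 21 of 25 members under the combination (22, 23, 24 and 21 adjusted over the list alone; camera adjusted p = 1.87e-146, 8.85e-111, 3.11e-66 and 7.1e-39). CRISPLD2 reached 5.13 ± 0.27 at 6 h. The cAMP and CREB-induced list rose in 11, 11 and 8 of 18 members at 1, 2 and 6 h, with 0, 1 and 2 falling (11, 12 and 8 rose and 0, 1 and 3 fell adjusted over the list alone; camera adjusted p = 6.88e-54, 1.3e-27 and 0.000217, the last with adjusted p = 0.106 with an estimated correlation). The phosphodiesterase PDE4B, in that list, fell by 1.13 ± 0.22 at 6 h. Fasting genes rose in 4, 12, 11 and 11 of 21 members, with 1, 1, 2 and 3 falling (6, 12, 11 and 11 rose and 1, 1, 2 and 3 fell adjusted over the list alone; camera adjusted p = 9.32e-05, 1.42e-13, 4.8e-13 and 6.69e-05). Metallothioneins rose in 4, 8, 8 and 6 of 9 members (6, 8, 8 and 7 adjusted over the list alone; camera adjusted p = 4.03e-16, 4.39e-19, 4.42e-13 and 7.6e-05, the last with adjusted p = 0.072 with an estimated correlation). MAPK phosphatases and feedback inhibitors rose in 8 of 16 members at 1 h and 6 at 2 h, with 1 and 3 falling (8 and 6 rose and 2 and 4 fell adjusted over the list alone; camera adjusted p = 5.37e-23 and 0.00113, the second with adjusted p = 0.0905 with an estimated correlation).

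Cytokines and chemokines rose in 7 of 26 members at 1 h under the combination (8 adjusted over the list alone; camera adjusted p = 1.66e-10), with CXCL2 at 4.19 ± 0.20. At 6 h 10 of 12 cholesterol genes fell (11 adjusted over the list alone; camera adjusted p = 6.83e-11), and HMGCS1 fell by 1.01 ± 0.11. At 18 h 6 fell (7 adjusted over the list alone; camera adjusted p = 0.00225, adjusted p = 0.106 with an estimated correlation). At 18 h 14 of 26 extracellular matrix genes fell and 3 rose (14 and 3 adjusted over the list alone; camera adjusted p = 6.45e-05). Of 17 heat shock genes 6 fell (9 adjusted over the list alone; camera adjusted p = 0.000896), and 7 of 18 epithelial genes fell and 3 rose (7 and 3 adjusted over the list alone; camera adjusted p = 0.00971). Immediate early factors fell in 7 of 18 members at 6 h and 6 at 18 h, with 2 and 1 higher (8 and 6 fell, with 2 and 1 higher, adjusted over the list alone; camera adjusted p = 0.000217 and 0.00778, the second with adjusted p = 0.082 with an estimated correlation). Cell division genes fell in 8 of 24 members at 2 h and rose in 2 (8 and 2 adjusted over the list alone; camera adjusted p = 0.0112, adjusted p = 0.181 with an estimated correlation). Regulators of G-protein signalling fell in 6 of 13 at 18 h and rose in 1 (6 and 1 adjusted over the list alone; camera adjusted p = 0.0202, adjusted p = 0.335 with an estimated correlation). The NF-kappaB list rose in 3 of 18 at 1 h (3 adjusted over the list alone; camera adjusted p = 0.000782, adjusted p = 0.194 with an estimated correlation). Among the 28 measured genes of the cAMP machinery 2 rose and 7 fell at 18 h (3 and 10 adjusted over the list alone), and the list passed in camera with the replicate block (adjusted p = 0.0451) and not without it (adjusted p = 0.0516).

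Combination against budesonide asked what formoterol adds to the glucocorticoid. The chemokine CXCL2 averaged 7.84 ± 0.23 (SD, n = 4) with the combination against 3.85 ± 0.19 with budesonide at 1 h, and the stress gene GADD45A averaged 11.16 ± 0.20 against 12.16 ± 0.11. At that time C11orf96 was higher by 3.99 ± 0.25, NR4A3 by 3.90 ± 0.16 and RGS2 by 3.53 ± 0.11. EGR1 was lower by a log2 change of −2.48 ± 0.19 and TXNIP by one of −1.53 ± 0.16. At 2 h NR4A3 was 4.99 ± 0.16 higher and the neuronal pentraxin NPTX1 3.91 ± 0.23, and the chromatin protein HMGA2 was lower at −1.60 ± 0.18. NPTX1 was 4.20 ± 0.23 higher at 6 h, with PID1 at 2.58 ± 0.14 and LTBP1, which binds latent TGF-beta, at 2.42 ± 0.15, and the oxytocin receptor OXTR lower at −1.52 ± 0.16. At 18 h the alcohol dehydrogenase ADH1B was 1.67 ± 0.13 higher and the acute phase gene SAA1 lower at −1.50 ± 0.20. The counts were 267, 794, 1218 and 118 genes at 1, 2, 6 and 18 h in limma. The replicate block gave 1886 at 6 h and 359 at 18 h, the block within each time, chosen after seeing the data, 437, 1532, 2587 and 665, and a fit of the compared arrays alone 501 at 2 h and 184 at 18 h. The 18 h count was 76 without budesonide replicate 2 and 77 without budesonide replicate 4, and 57 without all replicate 1 arrays.

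Combination against formoterol asked what budesonide adds to the agonist. IL6 was lower by log2 changes of −2.69 ± 0.19 at 1 h and −3.63 ± 0.19 at 2 h, and IL11 by −4.76 ± 0.20 at 6 h. CCL2 was lower at −3.78 ± 0.16 and CNR1 higher by at least 7.69 ± 0.16 at 6 h, and FKBP5 was higher by 2.89 ± 0.11 at 18 h. The counts in limma were 230, 753, 2433 and 3192 genes at 1, 2, 6 and 18 h. The block within each time, chosen after seeing the data, gave 379, 1219 and 3795 at 1, 2 and 6 h, though at 6 h not every same-numbered pair correlated above 0.1.

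The interaction of the drugs asked where the combination departed from the sum of both log2 effects. At 1 h PTGS2 exceeded the sum by 2.22 ± 0.29 and C11orf96 by 2.28 ± 0.35, with the small G protein RASD1 at 2.05 ± 0.22. For PTGS2, which averaged 2.96 in untreated cells, 4.18 with budesonide, 3.66 with formoterol and 7.11 with the combination, 2.22 is an upper bound because the untreated level was not told from background. SGK1 fell short of the sum at −2.47 ± 0.16, DDIT4 at −1.86 ± 0.22, DUSP1 at −1.51 ± 0.13 and NR4A3 at −1.39 ± 0.22. On the linear scale DUSP1 departed by 0.033, and DDIT4 by −0.17, neither past the threshold, and with all probe sets averaged DUSP1, at −1.07, did not pass. At 2 h C11orf96 and PTGS2 were again above the sum, at 2.67 ± 0.35 and 2.39 ± 0.29, with PTGS2 at 2.54 in untreated cells and 2.85 with formoterol, so that its size at 2 h has no bound. SGK1 stood at −2.25 ± 0.16, IL6 at −2.00 ± 0.27 and KLF9 at −1.87 ± 0.20, which on the linear scale was −0.12 and did not pass. At 6 h NPTX1 exceeded the sum by 2.34 ± 0.33, LTBP1 by 2.13 ± 0.22 and the protease PAPPA by 1.74 ± 0.28, and IL11 stood at −2.87 ± 0.29 and PDE7B at −1.83 ± 0.23. At 18 h ADH1B stood at 1.84 ± 0.18 and LINC00473 at −1.67 ± 0.28, and PCDH20, at 1.16 ± 0.25, was 1.02 and did not pass without combination replicate 2. ADH1B and PCDH20 averaged 2.34 and 2.70 in untreated cells and 2.18 and 2.68 with formoterol, so these sizes have no bound either. Without all replicate 1 arrays PCDH20, at 1.29, did not pass. PTPN13 at 18 h, at 1.13 ± 0.21, did not pass on the linear scale, where it departed by 1.30.

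The interaction was called for 31 genes at 1 h (14 higher, 17 lower), 107 at 2 h (65 higher, 42 lower), 131 at 6 h (81 higher, 50 lower) and 50 at 18 h (28 higher, 22 lower) in limma. The replicate block gave 48 and 162 at 1 and 2 h, and the block within each time 72 and 229. At 6 and 18 h, where not every same-numbered pair correlated above 0.1, they gave 272 and 167, and 428 and 339. Linear-scale additivity gave 61, 161 and 224 at 1, 2 and 6 h, and the compared arrays alone 65 at 2 h. Without formoterol replicate 1 at 18 h 79 passed, and without all replicate 1 arrays 18, 57, 84 and 22 passed at 1, 2, 6 and 18 h. The cAMP and CREB-induced list lay below the sum at 1 and 2 h, with 2 and 3 of 18 members called lower (4 and 7 lower and 0 and 1 higher adjusted over the list alone; camera adjusted p = 1.49e-13 and 1.14e-13). For glucocorticoid-induced genes 3 of 25 members were lower at both 1 and 2 h (3 and 9 lower and 2 and 5 higher adjusted over the list alone; camera adjusted p = 0.00171 and 1.73e-05, adjusted p = 0.36 and 0.156 with an estimated correlation). Fasting genes lay above the sum at 6 h with 1 of 21 called, LPIN1 (5 adjusted over the list alone; camera adjusted p = 3.06e-05). Epithelial genes lay above it at 2 h with 1 of 18, CLDN1 at 0.98 ± 0.22 (2 adjusted over the list alone; camera adjusted p = 0.00266), which did not pass without all replicate 1 arrays (0.93). Heat shock genes were above the sum at 18 h with 1 of 17 called, ASNS at 0.77 ± 0.11 (2 adjusted over the list alone; camera adjusted p = 0.00136). With the replicate block camera also called immediate early factors (adjusted p = 0.0244, against 0.0575 without it) and cytokines (adjusted p = 0.0433, against 0.0692) at 1 h and fasting genes (adjusted p = 0.0465, against 0.0814) at 2 h.

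Other interaction calls of lists were lost with an estimated correlation. They were metallothioneins at 1, 2 and 6 h, with 0, 0 and 1 of 9 members higher (1, 1 and 1 adjusted over the list alone; camera adjusted p = 0.0115, 0.00294 and 0.00686, adjusted p = 0.308, 0.211 and 0.271 with an estimated correlation). Cytokines at 2 h had 2 of 26 lower (3 lower and 1 higher adjusted over the list alone; camera adjusted p = 0.00481, adjusted p = 0.106 with an estimated correlation). Regulators of G-protein signalling at 2 h had 0 of 13 called (1 higher adjusted over the list alone; camera adjusted p = 0.0282, adjusted p = 0.372 with an estimated correlation). Heat shock genes at 2 h had 1 of 17 higher (1 adjusted over the list alone; camera adjusted p = 0.0256, adjusted p = 0.183 with an estimated correlation). The cAMP and CREB-induced list at 18 h had 2 of 18 lower and 1 higher (4 and 1 adjusted over the list alone; camera adjusted p = 0.00877, adjusted p = 0.302 with an estimated correlation). Of all 336 list tests camera called 94, and 56 of those held with an estimated correlation. The median and the test differed in sign for cytokines under budesonide at 2 h (median 0.03), the NF-kappaB list under the combination at 1 h (−0.05), clock genes under formoterol at 1 h (−0.01) and glucocorticoid-induced genes in the 2 h interaction (0.05).

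Budesonide and formoterol were also set against each other. IL11 fell by 2.20 ± 0.20 with budesonide and rose by 3.90 ± 0.20 with formoterol at 2 h. PDE4B fell by 2.07 ± 0.22 or more with budesonide, to 2.55, and rose by 1.93 ± 0.22 with formoterol at 2 h. CCL2 fell by 3.29 ± 0.16 and rose by 1.66 ± 0.16 at 6 h. Genes lower with budesonide and higher with formoterol numbered 23, 63, 108 and 13 at 1, 2, 6 and 18 h. Independent lists would share 0.612, 9.45, 40.6 and 8.31. With the untreated arrays split between the drugs the means were 12.5, 40.5, 75.8 and 7.17, where independent lists would share 0.278, 4.30, 23.1 and 3.12. Unchanged groups against the same controls shared 0 in simulation. With no gene changed hardly any gene is called, so this 0, here and below, was fixed in advance. It decides nothing about noise in shared controls. Genes higher with budesonide and lower with formoterol numbered 3, 33, 38 and 6 (independent lists 0.387, 7.004, 22.8 and 9.93; simulation 0), and with split controls 1.83, 19.3, 24.7 and 1.5 against 0.140, 3.13, 12.3 and 2.86. Both drugs raised 44, 76, 129 and 35 genes (independent lists 1.23, 7.07, 30.6 and 7.28; split controls 26.7, 49.8, 78.0 and 14.0 against 0.745, 4.14, 16.3 and 2.51; simulation 0). Both lowered 9, 70, 196 and 93 (independent lists 0.192, 9.36, 30.3 and 11.3; split controls 1.67, 26.2, 110 and 31.3 against 0.0520, 3.17, 15.4 and 3.29; simulation 0). Across genes, which are not independent replicates, the fold changes correlated at 0.301, 0.258, 0.188 and 0.353 against 0.503, 0.503, 0.500 and 0.500 in simulated unchanged groups, and 0.0692, 0.0928, 0.0776 and 0.202 with split controls. Their covariance was 0.00968, 0.0140, 0.0136 and 0.0216 against a simulated 0.00767, 0.00765, 0.00756 and 0.00759. The simulation drew groups independently, without the shared deviations of same-numbered arrays, so its correlations and covariances are no exact reference for these arrays.

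The tests of change over time asked whether an effect differed between 1, 2, 6 and 18 h. The budesonide effect on CNR1 (limma F test, adjusted p = 1.39e-35) and FKBP5 (adjusted p = 3.53e-23) differed between times, and that on IL6 did not pass (adjusted p = 0.868). The formoterol effect on NR4A3 (adjusted p = 5.50e-30), PDE7B (adjusted p = 1.32e-22) and IL6 (adjusted p = 2.78e-21) differed. Such differences were called for 2305 genes with budesonide, 818 with formoterol and 4106 with the combination. The replicate block gave 1450 for formoterol, a fit without the replicate 1 arrays 539, and the block within each time 4284, 2374 and 6321. Of the budesonide calls at 6 h, 640 higher and 895 lower genes were called the same way at 18 h, where independent lists would share 95.0 and 144. For formoterol these shared numbers were 50 and 54, against 2.34 and 2.39 for independent lists.

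Untreated cells at 18 h were compared with those at 1 h for change with time alone. EGR1 fell by 1.91 ± 0.19 and the keratin-associated gene KRTAP2-3 fell by 1.32 ± 0.23, while THAP2 rose from a mean of 3.64 to 4.84 and PURG from 2.79, not told from background, to 3.79 (limma adjusted p = 0.000338 for each). PURG did not pass with all probe sets averaged (0.26), nor THAP2 with the compared arrays alone (adjusted p = 0.0536). These 4 genes were the ones changed at least 2-fold, and EGR1 belongs to a list while the others were chosen after their values were seen. In limma 66 genes passed (41 higher, 25 lower), and 385 with the replicate block, 26 with the compared arrays alone and 36 with the mean of all probe sets. The count was 40 and 17 without untreated 1 h replicates 1 and 3, and 16, 27 and 39 without untreated 18 h replicates 1, 2 and 4. It was 8 without all replicate 1 arrays, where KRTAP2-3 (−1.22) and PURG (0.92) did not pass.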

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

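The regroupings of residuals for the interactions, the comparison of changes at 6 and 18 h and the test of linear additivity were chosen only after the results were seen.

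Within groups of 4 arrays, 6 of 64 array measures (9.38%, all of them 3' minus 5' signals) and 17 of 309 pairs of gene and group (5.50%) had one array far from the others, and chance gives about 1 in 20 such groups. Beta-actin 3' minus 5' signals were highest in replicate 1 in 12 of 12 groups at 1, 6 and 18 h and in replicate 3 in 4 of 4 at 2 h. The values that follow are the gap to the nearest other array divided by the range of the group. For the 3' minus 5' signal of GAPDH they were 0.877 with budesonide at 1 h, 0.849 with budesonide at 6 h, 0.853 with the combination at 6 h and 0.836 in untreated cells at 18 h. For beta-actin they were 0.884 with budesonide at 1 h and 0.900 with the combination at 6 h. In untreated cells they were 0.887 for C11orf96 and 0.919 for DUSP1 at 1 h, and 0.850 for CD200, 0.902 for EGR1, 0.903 for PTGS2 and 0.860 for TSC22D3 at 2 h. With budesonide they were 0.871 for IER3 and 0.840 for TSC22D3 at 1 h, 0.917 for TXNIP at 2 h and 0.902 for LTBP1 at 18 h. With formoterol they were 0.855 for DUSP1 and 0.899 for NR4A2 at 1 h, 0.845 for FGF5 and 0.859 for PTGS2 at 2 h and 0.837 for LINC00473 at 18 h, and with the combination 0.837 for TSC22D3 at 2 h and 0.943 for IL11 at 18 h.

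Effects differed between times by the limma F test for 2305 genes with budesonide, 818 with formoterol and 4106 with the combination. Among 4305 probe sets with several gene symbols or none, which the gene tests left out, and without the array's control probe sets, limma called 17, 74, 317 and 447 with budesonide at 1, 2, 6 and 18 h. The numbers were 33, 76, 73 and 4 with formoterol and 42, 173, 409 and 515 with the combination.

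The formoterol effect on genes called at 6 h was smaller at 18 h. Genes called at 6 h in one set of replicates had a median change of 0.61 at 6 h in the other set. At 18 h their median change over all replicates was 0.17, a ratio of 0.283 with a 95% interval of 0.253 to 0.311. The 793 entries pool both choices of the set, so a gene can enter more than once. The interval treats entries as independent and does not measure the spread between arrays. For the combination against budesonide the ratio was 0.137 (0.114 to 0.159; 997 such entries; medians 0.56 and 0.08). The fit estimated one spread per gene over all arrays, with a median SE of 0.116 for both comparisons at 6 h and at 18 h. A wider spread of the 18 h arrays could thus not lower the counts through a larger SE. The ratios show that the changes of the genes called at 6 h were smaller at 18 h. As genes were chosen at 6 h only, the ratios do not cover genes that respond at 18 h alone. A loss of response to the drug, or of the drug itself, over time may be the cause and was not tested.

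Genes raised by both drugs mostly fell short of the sum of the log2 effects. With genes chosen in one set of replicates the median interaction in the others was −0.31 (95% interval −0.39 to −0.23; 279 entries). Entries pool times and both choices of the set, so a gene can enter more than once. The intervals here treat entries as independent and do not measure the spread between arrays. By time this median was −0.29, −0.41, −0.13 and −0.48 at 1, 2, 6 and 18 h. It argues against choice on shared control noise, least so at 6 h, where it was near the bound of −0.1 set for that test. Over genes called with all replicates, each entering once for every time at which both drugs raised it, the median was −0.17 (−0.24 to −0.13; 284 entries). Below the 95th percentile of signal it was −0.15 (−0.20 to −0.11; 223 entries) and at or above it −0.47 (−0.52 to −0.16; 61 entries), which leaves a ceiling of the arrays open. Against the sum on the linear scale the median departure of the held-out entries was 0.12 (0.06 to 0.17). By time it was 0.34 (0.028 to 0.53), 0.11 (0.011 to 0.19), 0.15 (0.065 to 0.20) and −0.11 (−0.23 to 0.0040; 17 entries) at 1, 2, 6 and 18 h. The median thus lay above the linear sum at 1, 2 and 6 h, and 18 h stays open. The one-sided bound of −0.1 set for the test could not show such a departure. As the intervals do not measure the spread between arrays, plain addition on that scale was not excluded.

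Genes raised by formoterol were often lowered by budesonide, though more were raised by both drugs at each time. Those lowered by budesonide numbered 23, 63, 108 and 13, and those raised by both 44, 76, 129 and 35, at 1, 2, 6 and 18 h. With separate untreated arrays for each drug the number raised by formoterol and lowered by budesonide was 9.42 times that of independent lists at 2 h and 3.28 times at 6 h. Noise in shared controls moves both changes the same way, so that test could not have come out otherwise and decides nothing. Against draws matched on level and spread the ratios were 4.44 and 1.74, with 63 and 108 genes against at most 25 and 93 in 1000 draws. The second ratio was below the bound of 2 set for that test, so level and spread may account for part of the overlap. Opposing regulation of one set of genes by both drugs was not tested.

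Other splits of the same arrays gave the following numbers of genes. For every comparison of a pair of groups except formoterol at 18 h, the real split was 1 of 35 with so many genes, which excludes chance if arrays of one comparison are interchangeable, and the highest other counts are in brackets. They were 181 (47), 715 (178), 2583 (957) and 3325 (883) for budesonide at 1, 2, 6 and 18 h, 243 (66), 834 (212) and 873 (307) for formoterol at 1, 2 and 6 h, and 500 (138), 1721 (441), 3366 (1268) and 3807 (817) for the combination. Against budesonide the combination gave 267 (48), 794 (161), 1218 (108) and 118 (16), against formoterol 230 (73), 753 (235), 2433 (705) and 3192 (988), and untreated cells 66 (1). Every same-numbered pair correlated above 0.1 in 18 of these 21 comparisons. Only 7 other splits part the pairs as the real one does, which is too few for a share under 0.05. Those splits leave arrays of both treatments on each side, and their highest counts at 1, 2, 6 and 18 h were 7, 14, 300 and 284 for budesonide and 58, 101, 499 and 516 for the combination. They were 0, 37, 2 and 2 for the combination against budesonide, 17, 38 and 1 for formoterol at 1, 2 and 6 h, 8 and 32 for the combination against formoterol at 1 and 2 h, and 0 for untreated cells. For formoterol at 18 h 2 of 35 splits gave 201 or more, so this test did not exclude chance. The other one, with 457, put untreated replicates 1, 2 and 4 beside formoterol replicate 1. The 7 splits that part same-numbered arrays gave at most 3. Of the genes called at 18 h, 50 higher and 54 lower were called the same way at 6 h, on other arrays. Independent lists would share 2.34 and 2.39, and 2 genes were called in opposite directions. These values argue against chance for the shared genes. The F tests over times had 1 of 100 regroupings each, against highest others of 1352, 234 and 963, which excludes chance on the same condition, since replicate numbers were not kept together.

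For the interactions 23, 20, 19 and 14 of 100 regroupings at 1, 2, 6 and 18 h gave at least the real 31, 107, 131 and 50 genes, with highest others of 325, 778, 2403 and 2091, so this test did not exclude chance. Regrouped arrays of different treatments carry the drug effects into the contrast, and a second test, added after seeing these counts, regrouped what was left after removing additive effects. It gave 1, 2, 2 and 2 of 100, with highest others of 7, 408, 140 and 341, but did not keep replicate numbers together. Regrouping these residuals only among arrays of one replicate number gave 1 of 100 at each time, with highest others of 16, 32, 40 and 19. In both tests the additive effects were removed with the real labels, which can favour the real grouping. The last test was also chosen after the first had left chance open. Its counts argue against chance but do not exclude it.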

How the results depend on the processing

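The block within each time and the fit without all replicate 1 arrays were chosen only after seeing the data, and the other alternatives were planned. The 227 gene values tested kept their direction and their side of the threshold in all cases with arrays centred on their medians, the replicate block, dim genes left out (226 values, without PURG) and, for the 223 where it applies, the block within each time. With repeated quantile normalization or no intensity trend 226 did, with the compared arrays alone 224 and with the mean of all probe sets 220, and the calls that ended, 1, 1, 3 and 7, kept their direction. Other scalings moved the share of higher calls by at most 7.71 percentage points. Where no cause is given, the cause was not tested. The arrays' signal over background limits what can be said of dim genes.

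With the replicate number as a block, counts moved for the interaction at 1 h (48), 2 h (162), 6 h (272) and 18 h (167), formoterol at 6 h (1360) and 18 h (527), the combination against budesonide at 6 h (1886) and 18 h (359), untreated cells (385) and formoterol over times (1450). The numbers do not pair the arrays by the check for the combination against formoterol and the interaction at 6 h (lowest correlations 0.0767 and −0.0774) or at 18 h (both −0.0695), nor for formoterol at 18 h (−0.0628). In those unpaired contrasts the block called metallothioneins with formoterol at 18 h (camera adjusted p = 0.0216) and cell division (0.0244), extracellular matrix (0.0285) and metallothionein genes (0.0306) in the interaction at 18 h. Over all lists it called 100, 92 of them also called without it, and besides the calls given with their results it changed no other call.

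With a block within each time, at 1 h 312 genes passed for budesonide, 557 for formoterol, 966 for the combination, 437 against budesonide, 379 against formoterol and 72 for the interaction. At 2 h these were 1379, 1637, 2794, 1532, 1219 and 229. At 6 h budesonide gave 4081, formoterol 1910, the combination against budesonide 2587 and against formoterol 3795, and the interaction 428. At 18 h formoterol gave 965, the combination against budesonide 665 and the interaction 339, and over times the numbers were 4284, 2374 and 6321. The block takes up spread shared by same-numbered arrays of a time.

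Without all replicate 1 arrays, which leaves 3 arrays a group, the interactions numbered 18, 57, 84 and 22 at 1, 2, 6 and 18 h, the combination against budesonide at 18 h 57, untreated cells 8 and formoterol over times 539. Of the gene values 218 kept their call and 9 lost it in the same direction.

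The mean of all probe sets gave 36 genes for untreated cells at 18 h against 1 h. The compared arrays alone, which estimate the spread from fewer samples, gave 436, 470, 501 and 65 at 2 h for budesonide, formoterol, the combination against budesonide and the interaction, 77 and 184 at 18 h for formoterol and the combination against budesonide, and 26 for untreated cells. Additivity on the linear scale gave 61, 161 and 224 interactions at 1, 2 and 6 h and turned the direction of DUSP1 at 1 h (0.033). It ended the calls of DDIT4 at 1 h (−0.17), KLF9 (−0.12) and FLRT3 (−0.67) at 2 h and PTPN13 at 18 h (1.30), and the mean of all probe sets ended those of PPP1R3B (0.89) and DUSP1 (−1.07) in the interaction at 1 h. With an estimated correlation 56 list tests were called.

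With each array left out in turn, untreated cells gave 16 to 80 genes, with 40 and 17 without 1 h replicates 1 and 3 and 16, 27 and 39 without 18 h replicates 1, 2 and 4. Formoterol at 18 h gave 93 to 348, with 121 without untreated replicate 2 and 348, 117 and 93 without formoterol replicates 1, 2 and 4. The combination against budesonide at 18 h gave 76 to 115, with 76 and 77 without budesonide replicates 2 and 4. The interaction at 18 h gave 35 to 79, with 79 without formoterol replicate 1. Of single gene values with one array left out, 2075 kept their call and 13 lost it in the same direction, 3 each for CXCL8, NR3C1 and RPL3 and 2 for RPL13 among them. SERPINB7 (−0.97) with formoterol at 18 h did not pass without formoterol replicate 4, nor PCDH20 (1.02) in the interaction at 18 h without combination replicate 2.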

Other observations

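The gene and list tests in this part were planned, the fit without all replicate 1 arrays was chosen only after seeing the data, and the example genes were picked from the lists after their values were seen.

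Circadian clock genes moved both ways under budesonide. The period gene PER1 rose by 3.61 ± 0.28 at 2 h and NPAS2, a partner of BMAL1, by 2.24 ± 0.11 at 18 h. PER2 rose by 0.90 ± 0.16 at 6 h and fell by 0.80 ± 0.16 at 18 h, which did not pass with all probe sets averaged (−0.14). BMAL1 fell by 0.48 ± 0.11 at 6 h and rose by 0.60 ± 0.11 at 18 h. Their limma F tests over times gave adjusted p = 5.67e-07 and 4.61e-06. Of 17 measured clock genes 6 rose and 4 fell at 6 h, and 4 rose and 7 fell at 18 h (9 and 6, then 4 and 8, adjusted over the list alone), and camera called neither (adjusted p = 0.156 and 0.496). Under formoterol 3 rose at 1 h (3 with 1 falling adjusted over the list alone; camera adjusted p = 0.0113, adjusted p = 0.262 with an estimated correlation), BHLHE40, a transcriptional repressor, by 2.48 ± 0.25.

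Of 22 interferon-stimulated genes 2 fell with budesonide at 2 h and 5 at 18 h (2 and 5 adjusted over the list alone; camera adjusted p = 0.00336 and 0.032, adjusted p = 0.604 and 0.722 with an estimated correlation). The transcription factor IRF1 fell by 0.81 ± 0.11 at 2 h and IFIT2 fell by 1.24 ± 0.26 at 6 h. With formoterol 1 rose at 6 h, the exonuclease gene ISG20 at 2.08 ± 0.13 (1 adjusted over the list alone; camera adjusted p = 0.014, adjusted p = 0.67 with an estimated correlation). In the interaction 1 was above the sum at 2 h (1 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.00365, adjusted p = 0.604 with an estimated correlation). Camera called no test of the 14 leukocyte, 10 endothelial, 12 fibroblast and smooth muscle or 16 ribosomal genes, with lowest adjusted p of 0.0943, 0.203, 0.339 and 0.0925. The mean level of 3, 1, 5 and 16 of these lay above the median of all probe sets, which is no measure of expression since levels of different probe sets are not comparable. PDGFRB averaged 8.68 and THY1 7.66. At 18 h with budesonide PDGFRB rose by 0.60 ± 0.12, which did not pass with all probe sets averaged (0.19), THY1 fell by 0.98 ± 0.10 and the endothelial marker ENG fell by 0.73 ± 0.11. The ribosomal genes RPL13 and RPL3 rose by 0.22 ± 0.07 and 0.17 ± 0.06, and neither passed without budesonide replicate 2 (0.18 and 0.16) or 4 (0.19 and 0.15) or all replicate 1 arrays (0.23 and 0.13). RPL3 also did not pass without untreated replicate 1 (0.10), without the intensity trend (0.17), with quantile normalization repeated (0.16), with all probe sets averaged (0.15) or with the compared arrays alone (0.17). Of the 25 glucocorticoid-induced genes 11 also stood in another list, as did 11 of the 18 cAMP and CREB-induced genes.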
